A study of Homo sapiens with 123 samples.

How the data were processed

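Total RNA from medium spiny neuron-like cells, differentiated from the human embryonic stem cell lines H1 and H9, was sequenced as 123 libraries in 41 groups of 3. The labels number the replicates and do not say whether each is a separate culture. The deposited values are whole read counts per Ensembl gene, 1 table per library, given per the file headers as unique and total gene, exon and intron reads. They are not scaled to depth: column sums differ between libraries, and exon reads plus intron reads equal gene reads in each table. The genome build is hg38, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. The tables hold 60676 genes with symbols and positions as the files pair them.

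Total gene reads were used for every comparison. Genes with low counts were removed with edgeR's filterByExpr at its default settings, libraries were scaled by the trimmed mean of M values, and a negative binomial model with 1 mean per group was fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust). The H1 exposure groups (48 libraries), the H9 exposure groups (15), and the H1 and H9 preincubation groups (30 each) were fitted separately, and differences between the lines in fits that held both. Each of the 53 comparisons was a contrast in these fits, its two-sided quasi-likelihood F test was adjusted over all genes tested by the method of Benjamini and Hochberg, and an adjusted p under 0.05 counted as passing. Dopamine, glutamate, antagonist and agonist groups were set against PBS, 5-day against single exposures, antagonist groups against dopamine alone, and agonists against each other. In the preincubation experiment, each tonic transmitter was set against tonic ascorbic acid with phasic ascorbic acid throughout. Phasic dopamine was set against phasic ascorbic acid within each preincubation, averaged over preincubations, and tested for differing among them. Standard errors were taken from the log2 change and its F statistic. All comparisons with PBS in a line share the same 3 PBS libraries.

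Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 32 lists in each comparison. Counts of passing list members are given over all genes tested and adjusted over the list alone. Named genes follow a rule also set before the data were examined. It takes up to 10 higher and 10 lower genes with the largest log2 change among those passing. These need a mean of at least 5 CPM and an established symbol. Between groups, or between a group and the rest of its file stamp, the libraries also had to be fully apart. This was not required for means over preincubations, differences between lines or fits without the mostly intronic H9 libraries. Genes named from those fits, or within a file stamp, come from comparisons chosen after the data were examined. The rule adds up to 4 passing members of each list and up to 2 that did not pass. It also adds 20 genes of dopamine signalling, activity and stress in every comparison. The text leaves out some of the genes the rule names. PEG3, HEPACAM, AQP4 and PCDHGB4 as markers of the file stamp were chosen after their values were seen.

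The test was checked on simulated counts with known changes in 200 genes, all with a mean of at least 5 CPM. Counts were drawn from the overall gene means, library sizes and dispersions of these data, without shifts shared within a library. Recovery in the real data, and for genes at lower levels, may be lower. For dopamine on 5 days against PBS in H9 the test recovered 75% of 100 genes changed 2-fold and 100% of 100 changed 4-fold among 25895 genes tested. For phasic dopamine after tonic ascorbic acid in H1 it recovered 61% and 98% among 27439, and for a response that differs among preincubations in H1 44% and 89% among 27447. In the last case the simulated change was confined to phasic dopamine after tonic dopamine, and other patterns of difference were not simulated. The median biological coefficient of variation of the H1 exposure libraries was 0.27 in total reads and 0.13 in exon reads, and that of the H9 exposure libraries 0.21 and 0.17.

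Alternatives set before the data were examined were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in the edgeR fit, no filter on low counts, uniquely mapped reads, the replicate number as a block, and leaving out each library in turn. For the difference between lines in the phasic response, 8 libraries drawn at random were left out in turn. Chosen after the data were examined were exon reads in place of total reads, leaving out the 9 H9 preincubation libraries with over 50% of reads in introns, both together, and the mean of the other 9 groups of the same file stamp as the reference. No pair of replicates agreed within counting error, since the chi-square per degree of freedom of the 123 pairs was at least 2.89. Other libraries that lay apart included replicate 3 of H9 tonic ascorbic acid with phasic dopamine (20.2 and 17.6 from the others, which differ by 5.67). Replicate 3 of H1 tonic acetylcholine with phasic dopamine did as well (32.4 and 26.2 from the others, which differ by 9.94).

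Files were read and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.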

Results

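RNA was sequenced from cultures of human neurons resembling medium spiny neurons, the GABA-releasing projection neurons of the striatum that receive dopamine. The cultures were differentiated from the embryonic stem cell lines H1 and H9. The labels define 41 groups of 3 libraries, 123 libraries in all, with 78 from H1 and 45 from H9. In the first experiment, cultures received phosphate-buffered saline (PBS) or 1 mM dopamine for 1 h, once or on each of 5 days, and RNA was taken directly or after a wait of 24 h or, in H1, of 2 weeks. Other H1 cultures received glutamate, the D1-type receptor antagonist SCH23390 or the D2-type antagonist sulpiride (250 µM each), or both antagonists followed by dopamine. Further H1 groups received the D1-type agonists SKF81297 or SKF82958 (50 µM each), the D2-type agonist quinpirole (20 µM), the adenosine receptor agonist CGS21680 (5 µM), or quinpirole with CGS21680. In the second experiment, cultures of both lines were held for 3 weeks in 100 µM ascorbic acid, 10 nM dopamine, 750 nM acetylcholine, 2 µM glutamate or all 3 transmitters, here called the tonic preincubation. They then received 100 µM ascorbic acid or 1 mM dopamine for 1 h, here called phasic.

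The 48 H1 libraries of the first experiment held 19021046 to 29043378 reads in genes, and 8.3% to 19.6% of these lay in introns. The 15 H9 libraries of that experiment held 15772477 to 25570334 reads, with 12.3% to 22.4% in introns. In the preincubation experiment, 30 H1 libraries held 21089666 to 28287370 reads (10.2% to 43.4% intronic) and 21 of the H9 libraries held 9624986 to 15801904 reads (11.5% to 18.4% intronic). The other 9 H9 libraries held 2243635 to 8574351 reads, of which 80.8% to 97.0% lay in introns. They were replicates 2 and 3 of tonic acetylcholine with phasic ascorbic acid, replicates 1 to 3 of tonic acetylcholine with phasic dopamine, replicate 3 of tonic glutamate with phasic ascorbic acid, and replicates 1 to 3 of the 3 transmitters with phasic ascorbic acid. Values below are log2 fold changes ± standard error of 3 libraries against 3, and levels are CPM (reads scaled to library size), mean ± SD, n = 3, unless stated otherwise. Nothing in the labels says that replicates came from separate differentiations, so the p-values measure the spread between these libraries, which may be technical.

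**Figure D1:**
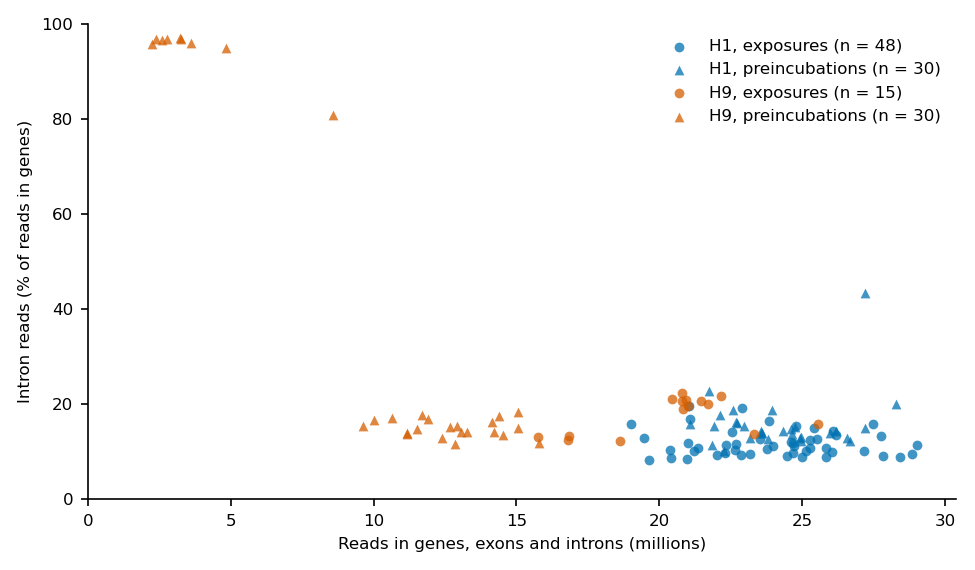
Reads in genes (horizontal axis) and the percent of them in introns (vertical axis) for each of the 123 libraries, coloured by experiment and line. The 9 H9 preincubation libraries stand apart at 80.8% to 97.0% intronic and at most 8574351 reads.

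After 1 h of dopamine, immediate early genes stood above PBS in H1 cultures. These are the transcription factors and signalling genes that neurons switch on within minutes of stimulation. FOS (ENSG00000170345, hg38 chromosome 14, 75278826 to 75282230) rose from 9.45 ± 1.46 to 220 ± 24.1 CPM, a log2 change of 4.54 ± 0.33. EGR1 (ENSG00000120738), another activity-induced transcription factor, rose from 24.2 ± 0.349 to 1027 ± 70.4 CPM (5.41 ± 0.28), and the neuron-specific factor NPAS4 rose by 5.43 ± 0.78. The matricellular genes CCN1 and CCN2 rose by 3.60 ± 0.15 and 3.23 ± 0.18, and GADD45B, a stress-induced regulator of growth arrest, by 2.78 ± 0.22. Of 31 immediate early genes measured, 23 rose and 0 fell (24 and 1 adjusted over the list alone; camera adjusted p = 3.1e-56, and adjusted p = 0.0019 with an estimated correlation).

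Several metabolic genes were lower after the same hour. The lactate transporter SLC16A3 fell by 3.65 ± 0.52, the aldolase ALDOC by 1.93 ± 0.32, the mTOR inhibitor DDIT4 by 1.71 ± 0.28 and TXNIP, an inhibitor of thioredoxin, by 2.01 ± 0.16. Of 23 hypoxia and HIF targets, 11 fell and 0 rose (16 fell adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). These genes varied among the PBS libraries themselves, with SLC16A3 at 20.1 ± 12.5 CPM and ALDOC at 58.8 ± 33.9 CPM. Of 46 cytosolic ribosomal protein genes, 44 fell (46 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), and 40 in exon reads. Among striatal genes, the dopamine-signalling phosphoprotein PPP1R1B fell by 1.20 ± 0.21 and the D2 receptor DRD2 by 0.88 ± 0.23, while the opioid peptide gene PENK rose by 1.29 ± 0.29. Among 30 striatal projection neuron markers, 1 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). In the H1 preincubation libraries with phasic dopamine (n = 15), DRD2 and PENK were low, at 3.26 ± 0.89 and 0.854 ± 0.32 CPM. There PPP1R1B stood at 105 ± 21.4 CPM and the cortical excitatory neuron marker NEUROD6 at 784 ± 145 CPM.

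Across all genes, edgeR's quasi-likelihood test placed 4526 of 27582 genes past an adjusted p of 0.05 after 1 h of dopamine in H1, 839 higher and 3687 lower. In exon reads alone the split was 2289 higher and 2891 lower, and the intron share was 14.13% ± 1.32 in the dopamine group and 10.67% ± 0.64 in PBS. Leaving out replicate 2 or 3 of the dopamine group gave 2289 or 2699 genes, and leaving out PBS replicate 3 gave 2656. The dopamine was dissolved in 100 µM ascorbic acid and the PBS was not, and the labels do not say on which day of differentiation the PBS groups were collected. Against phasic ascorbic acid, after tonic ascorbic acid in H1, FOS and EGR1 rose by 0.87 ± 0.25 and 0.87 ± 0.29 and did not pass. They stood at 25.9 ± 5.59 and 102.6 ± 19.7 CPM with phasic ascorbic acid. Vehicle and preincubation differ together between the experiments, so their shares in the rise over PBS cannot be told apart.

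H1 cultures collected 24 h after the single exposure differed from PBS more widely. EGR1 stood at 1712 ± 335 CPM (6.14 ± 0.29) and FOS at 234 ± 114 CPM (4.63 ± 0.33), and the monocarboxylate transporter SLC16A6 rose by 6.09 ± 0.31. DDIT3, which encodes the stress factor CHOP, rose by 2.59 ± 0.20, as did 17 other genes of 28 in the integrated stress and unfolded protein list, with 4 lower (18 and 6 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). The tubulin genes TUBA1A and TUBA1B fell by 4.47 ± 0.22 and 4.63 ± 0.23, and the mitochondrial gene MT-ND4 by 2.79 ± 0.19. All 13 mitochondrially encoded genes were lower, with a median of -3.27 (adjusted p = 0.13 with an estimated correlation), and they held 0.86% of reads against 2.32% in PBS. All 20 cell cycle genes fell, among them the topoisomerase TOP2A by 2.53 ± 0.19 (adjusted p = 0.13 with an estimated correlation). The test called 13745 genes, 5942 higher and 7803 lower, about as many as in exon reads (13353).

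After dopamine on 5 days, the immediate early response was smaller and neural progenitor and cell cycle genes were lower. EGR1 stood at 283 ± 77.8 CPM (3.55 ± 0.25) and FOS at 62.4 ± 10.9 CPM (2.73 ± 0.31). Directly against the single exposure, EGR1 had a log2 change of -1.86 ± 0.23, FOS of -1.81 ± 0.28, FOSB of -2.93 ± 0.43 and ATF3 of -1.27 ± 0.16. In that comparison 22 of 31 immediate early genes fell and 0 rose (24 adjusted over the list alone; adjusted p = 0.029 with an estimated correlation), while NPAS4 did not pass (-0.96 ± 0.56, adjusted p = 0.32). Also against the single exposure, the radial glia genes HES5 and SOX2 fell by 1.83 ± 0.35 and 1.35 ± 0.17 with 10 others of 14 neural progenitor markers (12 adjusted over the list alone; adjusted p = 0.0039 with an estimated correlation). All 20 cell cycle genes were lower than in PBS (adjusted p = 0.041 with an estimated correlation), as were 18 of 22 cholesterol synthesis genes (20 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), among them HMGCS1 by 0.98 ± 0.16.

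The antioxidant enzyme gene NQO1 (ENSG00000181019), a target of the stress factor NRF2, rose by 1.36 ± 0.19 after the 5 days. Against PBS, 11279 genes passed with 4310 higher and 6969 lower, against 6476 in exon reads (2893 and 3583), where PPP1R1B no longer passed (-0.37, against -0.85 ± 0.21). DESeq2 called 6293 higher and 5584 lower. The intron share was 18.1% ± 2.12 in this group and 10.7% ± 0.64 in PBS, and leaving out replicate 1 gave 7063 genes. The 5-day and 1 h groups differed in 3234 genes, 734 higher and 2500 lower (1354 and 2031 by DESeq2); without replicate 3 of the single exposure there were 2135 and without replicate 2 of the 5-day group 2058.

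When 24 h followed the 5 days, FOS and EGR1 did not pass against PBS, while NQO1, HMOX1 and CA9 still differed. FOS stood at 17.7 ± 4.09 CPM (0.91 ± 0.30, adjusted p = 0.053) and EGR1 at 31.6 ± 5.08 CPM (0.38 ± 0.24, adjusted p = 0.33), although both passed in exon reads (adjusted p = 0.0024 and 0.028). NQO1 stayed higher by 1.39 ± 0.19, with the haem oxygenase HMOX1 at 1.03 ± 0.23 and the acute-phase gene SERPINA3 at 1.46 ± 0.28. The carbonic anhydrase CA9 fell by 4.61 ± 0.73, ALDOC by 2.62 ± 0.34 and the angiogenic factor VEGFA by 2.18 ± 0.28, and 13 of 23 hypoxia targets fell (16 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). In the same PBS libraries CA9 varied as 7.05 ± 5.23 CPM and VEGFA as 150 ± 84.4 CPM. The test called 2523 genes, 441 higher and 2082 lower, 1193 and 1674 in exon reads, and 61 genes in a fit of this group and PBS alone. Without PBS replicate 1 or 3 it called 1404 or 1283, and without replicate 2 of the treated group 1333. Replicate 1 of the treated group stands apart, with 16.4% of reads in introns against 10.8% and 9.2% and a chi-square per degree of freedom of 49.3 and 83.6 from the others, which differ by 11.8; without it the count was 3511.

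**Figure D2:**
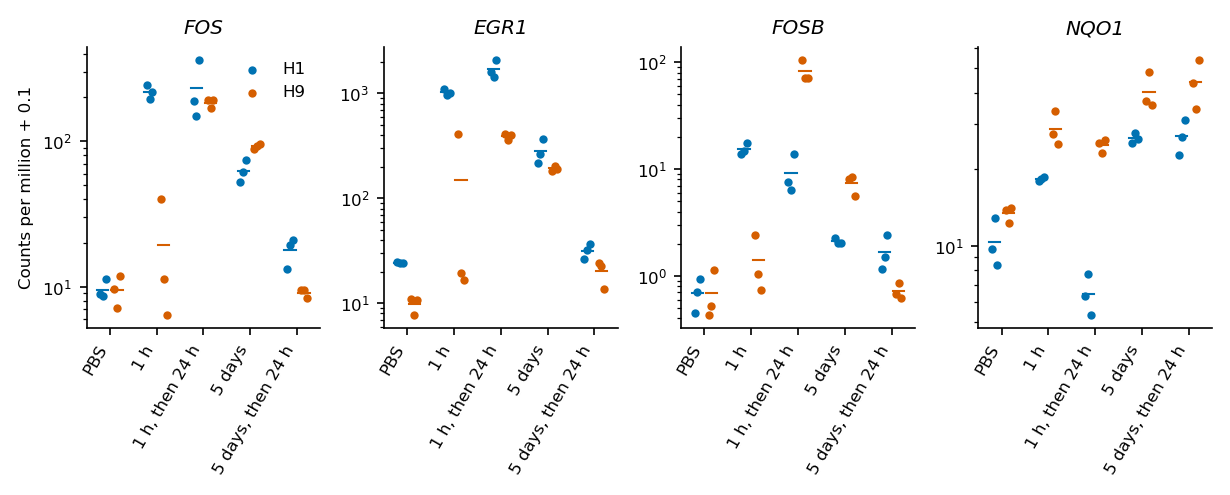
CPM of named genes (log axis) in each library of the PBS and dopamine groups of both lines, with the group means as bars. FOS and EGR1 lie far above PBS in H1 after 1 h and 24 h after the single exposure, and in the H9 group labelled 24 h. They lie near PBS 24 h after the 5-day exposure in both lines.

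Glutamate for 1 h, the main excitatory transmitter of the striatum's inputs, also raised activity genes in H1. EGR1 rose by 4.47 ± 0.26 to 536 ± 44.6 CPM, FOS by 3.40 ± 0.31, the synaptic gene ARC by 2.20 ± 0.29 and the stress peptide gene CRH by 2.17 ± 0.32. Of 31 immediate early genes 22 rose and 1 fell (24 and 2 adjusted over the list alone; adjusted p = 0.029 with an estimated correlation). GABA receptor genes were lower, with 9 of 15 falling and 0 rising (10 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation), among them GABRA2 by 1.29 ± 0.15 and GABBR2 by 0.63 ± 0.13. The matrix protease MMP3 fell by 5.20 ± 0.48, while DRD1, DRD2 and PPP1R1B did not pass. The test called 4995 genes, 1185 higher and 3810 lower (2669 and 3753 in exon reads), and 3229 without replicate 3 of the glutamate group. The sample labels give 1 mM glutamate and the treatment text 5 µM, so the dose is uncertain.

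The other 10 H1 groups carry another date stamp in their file names than the PBS, dopamine and glutamate groups, and no PBS group shares it, so their treatments and that batch cannot be told apart against PBS. All 30 of these libraries lay apart from the 18 others in 449 of 18919 genes in exon reads, 279 higher and 170 lower. The imprinted zinc finger gene PEG3 (ENSG00000198300, hg38 chromosome 19, 56810077 to 56840728) stood at 1.13 ± 0.514 CPM over the 30 libraries and 48.5 ± 8.29 CPM over the 18, a log2 difference of -5.31. The astroglial genes HEPACAM and AQP4 differed by 3.18 and 2.82, and the protocadherin PCDHGB4 by -3.44. Because of this, each of the 10 groups was also set against the mean of the other 9, an addition made after the data were examined.

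**Figure D3:**
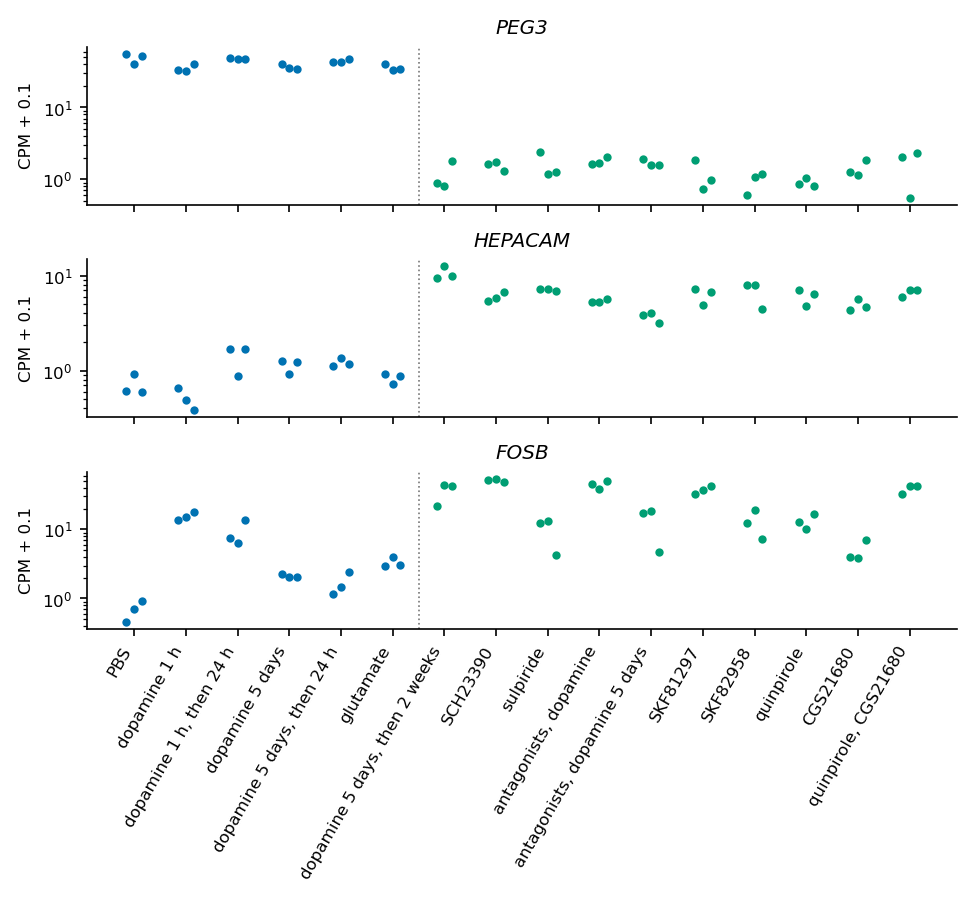
CPM (log axis) of PEG3, HEPACAM and FOSB, 1 point per library, groups on the horizontal axis. PEG3 and HEPACAM separate the 30 H1 libraries of the second file stamp from the 18 of the first. FOSB is shown beside them and was not chosen as a marker of the stamp. PEG3 is near 1 CPM in the second stamp and near 50 CPM in the first.

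H1 cultures collected 2 weeks after the 5-day exposure had FOSB higher than PBS by 5.91 ± 0.53, EGR1 by 4.22 ± 0.26 and ARC by 3.72 ± 0.30. Of 31 immediate early genes, 28 were higher and 0 lower (29 adjusted over the list alone; adjusted p = 0.00047 with an estimated correlation). All 20 cell cycle genes were lower, with a median of -2.08 (adjusted p = 9.3e-05 with an estimated correlation), and 9 of 13 astrocyte markers were higher with 1 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0086 with an estimated correlation). The D1 receptor DRD1 was higher by 2.54 ± 0.44, at 2.46 ± 0.148 CPM. Within its own stamp the group still differed from the other 9, with the stress cytokine GDF15 higher by 1.46 ± 0.15, the hypoxia factor EPAS1 by 1.35 ± 0.16 and NR4A1, an activity-induced nuclear receptor, by 1.30 ± 0.16. The mitotic kinase TTK had a log2 difference of -1.03 ± 0.18, and the GABA receptor subunit GABRA4 of -1.08 ± 0.23. PBS and this group differed in 5892 genes (2839 higher, 3053 lower), and the group and its own stamp in 5122.

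Each antagonist and the antagonists with dopamine also stood above PBS in immediate early genes: FOSB by 6.43 ± 0.53 after SCH23390 and 6.22 ± 0.53 after both antagonists with dopamine, and FOS by 2.69 ± 0.31 after sulpiride. Of 31 immediate early genes, 28, 21 and 30 were higher and 0, 1 and 0 lower after SCH23390, sulpiride and both antagonists with dopamine (28, 21 and 30 higher and 1 lower in each adjusted over the list alone; adjusted p = 0.00034, 0.11 and 0.00012 with an estimated correlation). Against PBS the test called 5942, 6950 and 6164 genes in these groups. Within the stamp, SCH23390 had higher FOS (1.11 ± 0.19), EGR1 (1.01 ± 0.15) and ZFP36, an mRNA decay factor (1.51 ± 0.12), with 13 of 31 early genes higher and 1 lower (18 and 3 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Sulpiride had lower CCN1 (-1.61 ± 0.12) and CCN2 (-1.41 ± 0.14), with 13 of the 31 lower and 0 higher (24 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). The ventral forebrain factor NKX2-1 was higher by 2.38 ± 0.32 after sulpiride, at 2.09 ± 1.66 CPM. Both antagonists with dopamine had the highest CCN1 and CCN2 within the stamp, higher than the other 9 groups by 2.26 ± 0.08 and 2.39 ± 0.10, with 17 of the 31 higher and 0 lower (23 and 1 adjusted over the list alone; adjusted p = 0.00039 with an estimated correlation). The 3 groups differed from the rest of the stamp in 907, 1069 and 1025 genes (1196, 244 and 1925 in exon reads).

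Set directly against dopamine alone, the antagonists with dopamine had EGR1 at -1.27 ± 0.23 and FOS at -0.99 ± 0.28, the corticotropin-releasing hormone gene CRH at -2.93 ± 0.33 and PENK at -2.61 ± 0.31. ARC was higher by 2.05 ± 0.27. This comparison crosses the file stamps, and PEG3 differed in it by -4.39 ± 0.28. It held 11161 genes, 5709 higher and 5452 lower, and 7289 without replicate 3 of the antagonist group. With the antagonists on each of the 5 days, low-oxygen genes were higher than after dopamine alone, SLC16A3 by 4.74 ± 0.54, CA9 by 4.26 ± 0.65 and VEGFA by 3.07 ± 0.29. In all, 21 of 23 hypoxia targets and 25 of 28 stress and unfolded protein genes were higher and 0 lower (22 and 26 adjusted over the list alone; adjusted p = 0.019 for each with an estimated correlation), and the astrocyte gene GFAP by 3.11 ± 0.25. FOS did not differ detectably (0.01 ± 0.28, adjusted p = 0.99). This comparison crosses the stamps as well and held 6141 genes, 4619 higher and 1522 lower (4005 and 2462 by DESeq2). Within the stamp the same group had higher A2M, a protease inhibitor (2.33 ± 0.12), SERPINA3 (1.79 ± 0.17) and the smooth muscle actin ACTA2 (1.89 ± 0.11) and differed in 5564 genes (3346 in exon reads); against PBS it differed in 5415.

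Between SKF81297 and SKF82958, tested at 50 µM for 1 h, genes passed in a number that depended on the fit and on single libraries. With SKF82958, FOSB was lower than with SKF81297 (-1.55 ± 0.38, not passing with the replicate number as a block), as were NR4A1 (-1.04 ± 0.24), NR4A2 (-1.11 ± 0.21) and CCN2 (-0.93 ± 0.16). The peptide gene NTS had -1.66 ± 0.27 and the keratin KRT18 -1.56 ± 0.24, while DLX2, a factor of GABAergic neuron development, was higher by 2.08 ± 0.36 and the secreted thrombospondin THBS1 by 1.26 ± 0.24. Of 31 immediate early genes 9 were lower and 0 higher (16 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), and of 12 choroid plexus and ciliated epithelium markers 4 were lower (6 adjusted over the list alone; adjusted p = 0.00032 with an estimated correlation). FOS and EGR1 did not pass, with differences of -0.58 and -0.06 and 95% intervals of -1.14 to -0.01 and of -0.52 to 0.41. The test called 261 genes, 121 higher and 140 lower (677 in exon reads), and in a fit of these 6 libraries alone 0. Each library left out in turn moved the count: 136, 114 and 162 without SKF81297 replicates 1 to 3, and 171, 91 and 756 without those of SKF82958. Replicate 3 of SKF82958 stands apart, with 15.8% of reads in introns against 8.4% and 8.3% and a chi-square per degree of freedom of 52.7 and 52.1 from the others, which differ by 5.71.

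Against the other 9 groups of the stamp, SKF81297 had higher NR4A1 (1.09 ± 0.16) and NR4A2 (1.38 ± 0.14), nuclear receptors induced by cAMP, with 8 of 31 early genes higher and 0 lower (14 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). Quinpirole had higher cell cycle genes, 11 of 20 and 0 lower (13 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), among them the proliferation marker MKI67 by 0.83 ± 0.12. CGS21680 had lower early genes, 29 of 31 (29 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), among them FOS (-1.55 ± 0.24) and EGR1 (-1.22 ± 0.19). Quinpirole with CGS21680 had higher NPAS4 (2.22 ± 0.35) and EGR4 (2.18 ± 0.20) and a lower arrestin-domain gene ARRDC3 (-1.40 ± 0.15). The 5 agonist groups SKF81297, SKF82958, quinpirole, CGS21680 and quinpirole with CGS21680 differed from the rest of the stamp in 277, 226, 1536, 11646 and 687 genes (1030, 909, 981, 1133 and 1677 in exon reads), and from PBS in 5370, 4236, 5845, 6756 and 5506. For CGS21680 against PBS, the split was 2491 higher and 4265 lower, and 3833 and 3958 by DESeq2; it fell to 3919 genes without CGS21680 replicate 1, and quinpirole against PBS to 3836 without quinpirole replicate 2.

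A pair of direct comparisons within the stamp set D1-type against D2-type agonists and tested the addition of CGS21680. SKF81297 exceeded quinpirole in NR4A1 (1.39 ± 0.24), FOSB (1.50 ± 0.38), DRD2 (1.02 ± 0.23) and NQO1 (1.05 ± 0.19), and the centromere gene CENPF was lower (-1.45 ± 0.21). Choroid plexus markers were higher, 7 of 12 and 0 lower (7 adjusted over the list alone; adjusted p = 0.0055 with an estimated correlation), with the choroid plexus transport protein TTR at 127 ± 16.9 against 21.0 ± 5.57 CPM. Adding CGS21680 to quinpirole raised NPAS4 by 2.53 ± 0.60, CRH by 1.85 ± 0.34, ANGPTL4, an inhibitor of lipoprotein lipase, by 2.39 ± 0.28 and PPP1R1B by 0.71 ± 0.21, and lowered TXNIP (-1.42 ± 0.16) and the neuronal factor POU3F2 (-1.41 ± 0.19). These comparisons held 1525 and 1541 genes (2352 and 2488 in exon reads), and counts without 1 library ran from 440 to 1958 and from 794 to 1338, lowest without SKF81297 replicate 3 and quinpirole replicate 1.

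In H9, the groups labelled 1 h and 24 h after a single exposure have file names that give the opposite times, so the labels are used here and the order stays in doubt. The libraries labelled 1 h had NQO1 (1.11 ± 0.17), the actin-binding gene TAGLN (2.71 ± 0.32) and HMOX1 (1.68 ± 0.45) above PBS, and FOS at 19.3 ± 18.4 CPM did not pass (1.01 ± 0.46, adjusted p = 0.088). EGR1 passed (3.93 ± 0.92) at 148 ± 225 CPM, with replicate 1 at 407 and the others at 19.5 and 16.5 CPM. Replicate 1 stands apart as a library, with 1.35% mitochondrial reads against 3.09% and 3.05% and a chi-square per degree of freedom of 121 and 109 from the others, which differ by 7.39. Without it the test called 13276 genes. The libraries labelled 24 h had FOSB at 82.4 ± 19.8 against 0.593 ± 0.379 CPM (7.11 ± 0.43), EGR3 higher by 6.41 ± 0.47, CCN2 by 5.13 ± 0.56 and FOS by 4.29 ± 0.49. Immediate early genes were higher in 18 of 31 and lower in 1 in the former (19 and 1 adjusted over the list alone) and higher in 27 in the latter (28), with adjusted p = 0.66 and 0.28 with an estimated correlation. Hypoxia targets fell in both, 20 of 23 each (20 and 22 adjusted over the list alone; adjusted p = 0.57 and 0.41 with an estimated correlation), with CA9 at -3.50 ± 0.49 and -3.26 ± 0.49. CA9 varied in the H9 PBS libraries as 11.8 ± 4.76 CPM, and the glucose transporter SLC2A1 as 158 ± 74.4. The groups held 11388 and 12264 genes of 26006 in all reads but 2690 and 2820 of 17804 in exon reads, and their intron shares were 14% ± 1.73 and 12.9% ± 0.49 against 20.8% ± 1.18 in PBS.

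Dopamine on 5 days in H9 raised EGR3 by 4.23 ± 0.45, FOS by 3.29 ± 0.47 to 92.1 ± 3.15 CPM, the cytokine signalling inhibitor SOCS3 by 3.97 ± 0.32 and GFAP by 1.63 ± 0.25. The metallothioneins MT1X and MT2A rose by 3.24 ± 0.42 and 1.78 ± 0.28, with 3 of 10 metal response genes higher (5 adjusted over the list alone; adjusted p = 0.0032 with an estimated correlation). Among NRF2 targets 4 of 27 rose (8 adjusted over the list alone; adjusted p = 0.0032 with an estimated correlation), led by NQO1 at 1.60 ± 0.17. HES5 fell by 1.48 ± 0.28, DDIT4 by 1.53 ± 0.29 and the hypoxia target ANKRD37 by 2.16 ± 0.43. The test called 259 genes, 151 higher and 108 lower, and between 32 and 128 without any 1 of the 6 libraries, lowest without PBS replicate 2. DESeq2 called 1005, and a fit of these 6 libraries alone called 4630, so the count depends strongly on the fit.

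In H9 collected 24 h after the 5 days, NRF2 targets were higher and hypoxia targets lower. NQO1 rose by 1.73 ± 0.17 to 44.0 ± 9.72 CPM, the thioredoxin reductase TXNRD1 by 0.64 ± 0.11 and the ferritin chains FTL and FTH1 by 0.58 ± 0.08 and 0.50 ± 0.08, with 5 of 27 NRF2 targets higher (10 adjusted over the list alone; adjusted p = 0.00014 with an estimated correlation). Hypoxia targets fell in 6 of 23 (23 adjusted over the list alone; adjusted p = 0.0046 with an estimated correlation), among them ANKRD37 by 2.80 ± 0.44, SLC2A1 by 2.03 ± 0.33 and the mitophagy gene BNIP3 by 1.68 ± 0.27. FOS (-0.06 ± 0.46) and EGR1 (1.06 ± 0.87) did not pass. The count was 42 genes, 9 higher and 33 lower (118 in exon reads, 385 by DESeq2), and fell to 2 without treated replicate 1 or PBS replicate 1 or 2. A fit of this group and PBS alone called 168. Against the libraries labelled 1 h, the 5-day libraries of H9 had FOS higher by 2.28 ± 0.45, FOSB by 2.57 ± 0.38, GFAP by 1.92 ± 0.25 and CA9 by 2.77 ± 0.48, in 9974 genes (1963 in exon reads).

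**Figure D4:**
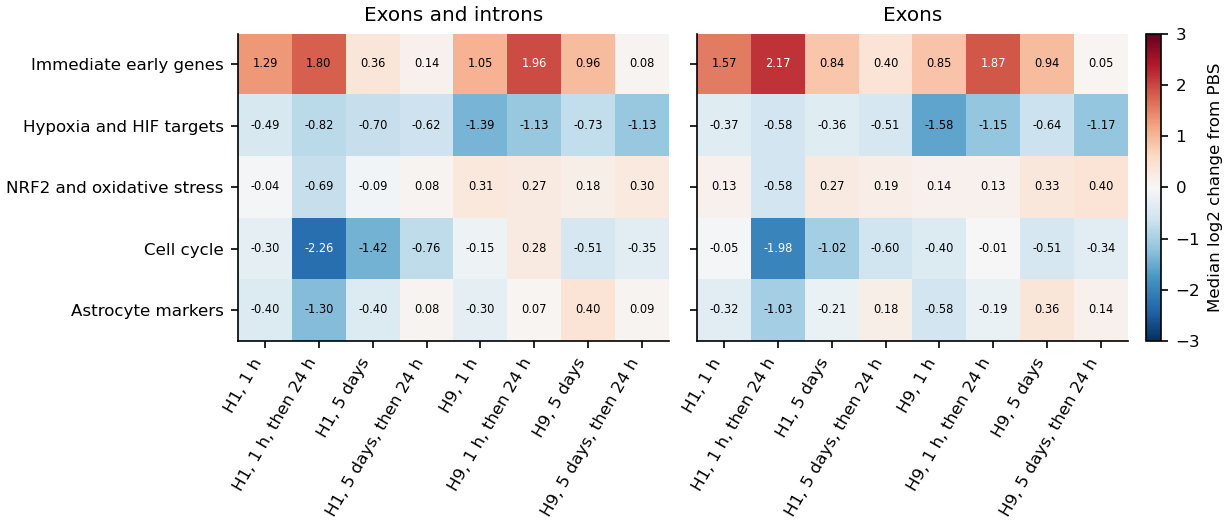
Median log2 change of 5 gene lists in the dopamine groups against PBS in H1 and H9, all gene reads and exon reads side by side. Hypoxia targets lie below 0 in all 8 comparisons and immediate early genes above 0.

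The lines had independent PBS groups, so their responses can be set side by side. Where both had dopamine on 5 days and 24 h of wait, NQO1 and SERPINA3 were the 2 genes higher in both, against 0.15 for unrelated lists, and 18 were lower in both against 2.68, among them ANKRD37, DDIT4 and BNIP3, with 0 opposite. In exon reads 12 were higher in both against 1.41 and 53 lower in both against 9.05. For the other exposures the 2 kinds of read gave different answers. After 5 days without the wait, 33 genes were higher in both against 24.5, 75 lower in both against 29.3 and 25 opposite (90 against 35.2, 69 against 28.3 and 15 in exon reads). After the hour labelled alike, 324 were higher in both against 153, but 484 were lower in both against 937 and 688 were opposite (520 against 186, 585 against 201 and 62 in exon reads). The correlation of the log2 changes across genes was 0.16, 0 and -0.38 for these 3 pairs in all reads and 0.36, 0.27 and 0.24 in exon reads, and genes are not independent replicates. For the groups labelled 24 h after 1 exposure it was -0.32 and 0.03, and 3555 and 810 genes moved in opposite directions.

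Tested directly as a difference of responses, H1 minus H9, the hour of dopamine raised FOS more in H1 (3.73 ± 0.58, n = 3 per group) and NPAS4 (6.15 ± 1.25), and HMOX1 less (-1.41 ± 0.51; -1.75 and not passing in exon reads), with the H9 group taken as labelled. For the 24 h groups TUBA1B differed by -5.04 ± 0.55 and EGR3 by -5.05 ± 0.60. After 5 days SOCS3 (-3.25 ± 0.37), EGR3 (-2.67 ± 0.60) and GFAP (-2.56 ± 0.34) rose less in H1 or fell, and neural progenitor markers were lower in 8 of 14 (10 adjusted over the list alone; adjusted p = 0.0058 with an estimated correlation). These differences held 10537, 18051 and 7813 genes in all reads and 600, 11214 and 1130 in exon reads, with 6962, 10340 and 5143 of the former higher; DESeq2 called 6053, 9796 and 4781 higher and 7862, 8297 and 4799 lower. For 5 days and 24 h of wait, edgeR called 0 genes, with 3115 at an unadjusted p under 0.05, 190 by DESeq2 and 8 in exon reads; without replicate 1 of the treated H1 group it called 608.

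In the preincubation experiment, few genes passed in H1 after 3 weeks of a tonic transmitter. Tonic dopamine at 10 nM lowered PDIA2, a protein disulfide isomerase, by 1.10 ± 0.14 (10.7 ± 0.693 against 22.9 ± 3.62 CPM), the 1 gene called; the call ended without replicate 1 of the dopamine group and in exon reads (-0.99). Tonic acetylcholine, glutamate and the 3 together gave 0 genes by edgeR, with 1121, 639 and 1308 at an unadjusted p under 0.05, and DESeq2 called 11, 8 and 23. In exon reads the counts were 2, 2 and 55. Fits of each group and tonic ascorbic acid alone called 302, 47, 0 and 134 genes for acetylcholine, dopamine, glutamate and the 3 together. Other splits of the same libraries reached 26, 9, 18 and 7, so the number of genes changed depends on the fit. Glutamate receptor genes had a median of 0.25 under acetylcholine with 0 of 22 past the threshold over all genes (3 adjusted over the list alone; adjusted p = 0.0011 with an estimated correlation).

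Phasic dopamine raised nuclear receptor and early genes in H1 after preincubation. Over the 5 preincubations, NR4A1 rose by 1.18 ± 0.11 (n = 15 per side), NR4A2 by 1.13 ± 0.09, EPAS1 (ENSG00000116016), the HIF-2α gene, by 1.08 ± 0.08, CCN2 by 0.98 ± 0.09 and FOS by 0.56 ± 0.11 (adjusted p = 0.041, and not passing with the replicate number as a block). EGR1 did not pass (0.41 ± 0.13, adjusted p = 0.92). All 26 called genes rose, among them 8 of 31 early genes (21 adjusted over the list alone; adjusted p = 0.0013 with an estimated correlation) and 2 of 22 cAMP targets (4 adjusted over the list alone; adjusted p = 0.002 with an estimated correlation). Singly, the preincubations gave 2, 2, 0, 4 and 1 genes after ascorbic acid, acetylcholine, dopamine, glutamate and the 3 transmitters. They were NR4A1 and EPAS1; NR4A2 and EPAS1; none (1245 at an unadjusted p under 0.05, 3 by DESeq2); NR4A2, CCN2, EPAS1 and ARHGAP29; and EPAS1. With the replicate number as a block, EPAS1 after acetylcholine and CCN2 after glutamate no longer passed. The test of a response that differs among preincubations called 0 genes by edgeR, 516 at an unadjusted p under 0.05 and 1 by DESeq2. Counts for single preincubations reached 0 when some libraries were left out, and the 26 ranged from 14 without replicate 3 of tonic with phasic ascorbic acid to 46 without replicate 3 of tonic with phasic dopamine. That library had 43.4% of reads in introns against 16% and 14.3% in the other 2 of its group, and without it the count after tonic dopamine was 3.

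H9 cultures raised immediate early genes after phasic dopamine, once the 9 mostly intronic libraries were set aside, a choice made after the data were examined. Over the 3 preincubations with libraries left (n = 9 against 8), CCN1 rose by 2.87 ± 0.10, CCN2 by 2.82 ± 0.21, FOSB by 2.67 ± 0.14, NR4A1 by 1.88 ± 0.10, FOS by 1.78 ± 0.08 and EGR1 by 1.23 ± 0.06, and the mitotic gene ASPM fell by 0.60 ± 0.12. EPAS1 and ARHGAP29 did not pass (0.05 ± 0.08 and 0.02 ± 0.10). Of 31 early genes 26 rose and 0 fell (28 adjusted over the list alone; adjusted p = 1.1e-06 with an estimated correlation). After tonic ascorbic acid, dopamine and glutamate, 17, 20 and 17 of them rose and FOS rose by 1.69 ± 0.14, 1.68 ± 0.14 and 1.98 ± 0.16, the last with 3 libraries against 2. After glutamate, cell cycle genes had a median of -0.66 with 2 of 20 past the threshold (16 adjusted over the list alone; adjusted p = 0.025 with an estimated correlation). Without the 9 libraries the test called 40, 387 and 45 genes after ascorbic acid, dopamine and glutamate, 545 pooled (319 higher, 226 lower; 253 higher and 134 lower after dopamine) and 2 that differed among preincubations, and 3 and 0 for tonic dopamine and glutamate (936 and 805 at an unadjusted p under 0.05), with 2 libraries left in the glutamate group. Tonic acetylcholine kept 1 library, too few for a test. In exon reads without them the phasic counts were 35, 1178 (557 higher, 621 lower) and 104, and 905 pooled (493 and 412).

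With all libraries the same H9 comparisons gave other counts: 21649 genes for the tonic 3 transmitters and 23050 for phasic dopamine after them, 0, 2, 0 and 1 after ascorbic acid, acetylcholine, dopamine and glutamate, 6650 pooled (678 higher, 5972 lower) and 12039 that differed among preincubations. Tonic acetylcholine, dopamine and glutamate gave 0 by edgeR (10705, 190 and 2923 at an unadjusted p under 0.05; 10235, 10 and 89 by DESeq2). The pooled count ranged from 7 without replicate 2 of tonic with phasic ascorbic acid to 19193, was 5074 in exon reads with 4135 higher, and was 7 with the replicate number as a block.

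Between the lines, phasic dopamine raised GADD45B (-1.96 ± 0.16, H1 minus H9), CCN1 (-1.93 ± 0.19), CCN2 (-1.70 ± 0.23), FOSB (-1.66 ± 0.27) and FOS (-1.01 ± 0.19) less in H1, and EPAS1 more (0.91 ± 0.13), when the 9 libraries were left out. Both lines were then averaged over tonic ascorbic acid, dopamine and glutamate alone, the preincubations left in H9. NR4A1 and EGR1 did not pass (-0.58 ± 0.19, adjusted p = 0.44, and -0.59 ± 0.21, adjusted p = 0.49). Of 31 early genes 10 rose less in H1 and 0 more (16 adjusted over the list alone; adjusted p = 0.0022 with an estimated correlation). The count was 18 genes of 30908, 3 higher and 15 lower, and 6241 with all libraries and all preincubations (5367 higher, 874 lower; 1006 and 6511 in exon reads). Libraries and preincubations changed together between these counts.

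**Figure D5:**
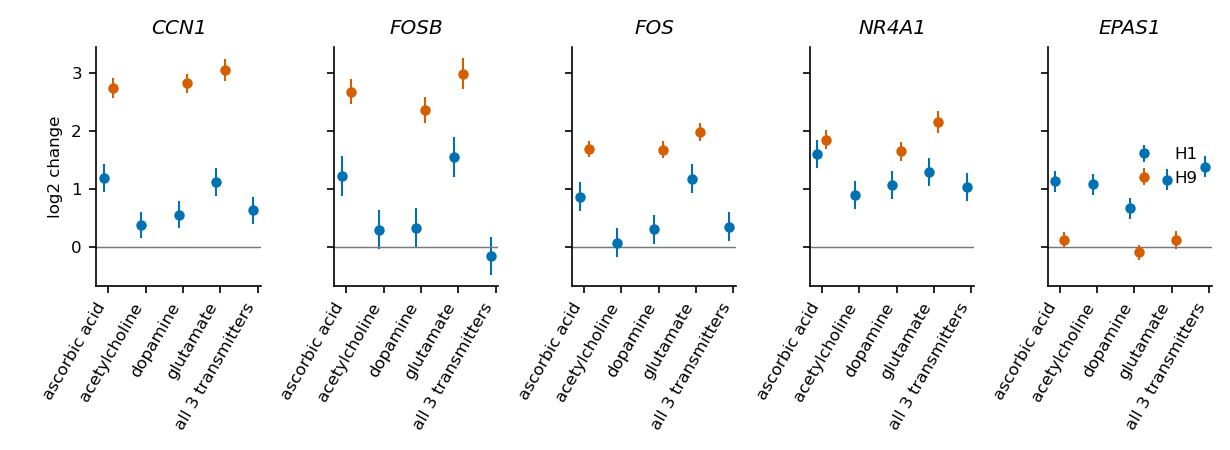
Log2 change ± standard error of CCN1, FOSB, FOS, NR4A1 and EPAS1 after 1 h of phasic dopamine in each tonic preincubation. H1 is shown with all libraries and H9 without the 9 mostly intronic ones, after ascorbic acid, dopamine and glutamate only. EPAS1 rises in H1 and lies near 0 in H9, while CCN1 and FOSB rise more in H9.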

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

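All tests of the order of the H9 groups, the ligand test of the file stamps and the 4 tests of the intronic libraries were chosen after the result was seen; the count of partitions of the stamps and all counts of splits were not.

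These 5 tests of a difference between groups drew attention by their size. The response to 1 h of dopamine differed between H1 and H9 in 10537 genes, that 24 h later in 18051, that to 5 days in 7813 and that to phasic dopamine in 6241. Within H9 the phasic response differed among preincubations in 12039 genes. Other splits drew the treated group anew within each line, or the phasic group anew within each line and preincubation; for the exposures the fit held the 12 libraries of each comparison alone. For the first of these, 1 of 100 splits was as large (real 11297, highest other 4052). For the next 2 it was 1 of 100 (18946 and 14861) and 2 of 100 (13745 and 13819). These splits mix treated and PBS libraries within each line and so remove the response itself. They cannot decide whether the responses of the lines differ beyond chance. For the phasic difference between lines 4 of 40 splits were as large (6236 and 8608) and for H9 preincubations 4 of 40 (12039 and 17997). Chance cannot be excluded there, these splits mix the phasic groups in the same way, and 9 of the H9 libraries were mostly intronic. Without those 9, over the preincubations left, the phasic counts were 18 between lines and 2 among H9 preincubations. In exon reads the line differences after 1 h, after 24 h and after 5 days held 600, 11214 and 1130 genes.

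The order of the H9 groups labelled 1 h and 24 h is open: the file names give the opposite times, and the group labelled 24 h has the higher FOS (192.9, 168.3 and 191.1 CPM of FOS in its libraries against 40.31, 11.19 and 6.263). If the labels were crossed, the change from the first to the second group should oppose the change over 24 h after 5 days, and the correlation across genes in exon reads was -0.32 in H9; the test needed a positive value in H1 as a reference, and H1 gave -0.19. If the labels were right and the lines differed, the H1 response at 1 h should follow the H9 group labelled 1 h, and its correlation exceeded that with the group labelled 24 h by -0.03 in exon reads (0.24 against 0.27; -0.38 against -0.39 in all reads). Crossed labels and a difference between lines cannot be told apart, because the H1 reference failed and the second value is under the 0.1 its test required. H1 after 24 h correlated at 0.48 with the group labelled 1 h and at 0.03 with that labelled 24 h in exon reads (-0.11 and -0.32 in all reads), but 1 library carries the former: from log2 CPM in exon reads, replicate 1 gave 0.76, replicates 2 and 3 gave 0.14 and 0.18, and the group gave 0.59 with replicate 1 and 0.17 without it.

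The 10 H1 groups of the second file stamp share a shift from the 6 others in 449 genes. A batch marked by the stamp may account for it: the real partition of the 16 groups into 10 and 6 was 1 of 100 partitions to separate as many genes, and the highest other separated 1. The tables argue against receptor ligands present at harvest as the whole cause, since the group collected 2 weeks after its last dopamine exposure shares the shift: SKF81297 against PBS correlated across genes at 0.76 with the 2-week against the 24 h group, above the highest of 630 pairs of contrasts inside the stamp (0.65); another pair between the stamps, both with ligands, gave 0.56 (SCH23390 against glutamate with SKF81297 against PBS). The stamp, the culture and the sequencing date cannot be separated, and no biological explanation other than the ligands was tested.

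The 9 mostly intronic H9 libraries span 4 of the 10 H9 preincubation groups. Genomic DNA in the library is a candidate source: long genes silent in the other libraries held intron reads per kb at 0.521 or more of the density in expressed genes, against at most 0.252 in the 21 others. Unspliced nuclear RNA would leave silent genes without reads, and the ratio reached 0.685 among the 9. In 2 of the 4 groups the other 3 libraries had at most 16.9% of reads in introns. For tonic glutamate these were 14.7% and 16.9%, so its treatment alone does not account for it. For tonic acetylcholine with phasic ascorbic acid it was 1 library at 15.3%, beside 96.7% and 95.7%, too few to decide. In the other 2 groups every library had at least 80.8%. The 3 transmitters with phasic dopamine held 17.0%, 14.1% and 11.9%, so these tonic transmitters alone do not account for the group with phasic ascorbic acid. Those libraries also had acetylcholine at 750 nM. With the 15.3% library, their values argue against tonic acetylcholine on its own as the cause. The combination with the phasic treatment stays open in the 2 groups where every library was mostly intronic.

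For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In a fit of the 6 libraries alone, splits with as many genes as the real one, the real included, numbered 1 of 10 except where another number is given, and each pair of values is the real split and the highest other. In H1 against PBS they were 10226 and 0 for dopamine, 16415 and 0 after 24 h, 14915 and 0 after 5 days, 61 and 1 after 5 days and 24 h, 6793 and 1 after 2 weeks, and 8117 and 2 for glutamate. For SCH23390, sulpiride, both antagonists with dopamine and the same on 5 days they were 8632 and 0, 10535 and 1, 9380 and 0, and 7259 and 0. For SKF81297, SKF82958, quinpirole, CGS21680 and quinpirole with CGS21680 they were 7297 and 0, 1731 and 0, 9343 and 0, 10105 and 0, and 7204 and 0. Antagonists with dopamine against dopamine gave 13870 and 0, the same on 5 days 6933 and 0, 5-day against single exposures 7116 and 2, SKF81297 against quinpirole 2771 and 0, and quinpirole with CGS21680 against quinpirole 2861 and 0. SKF82958 against SKF81297 gave 0 and 0 (10 of 10), against 261 genes in the fit of 48 libraries.

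In H9 the pairs were 5282 and 0 for the group labelled 1 h, 15270 and 0 for that labelled 24 h, 4630 and 2 after 5 days, 168 and 4 after 5 days and 24 h, and 3925 and 0 for 5-day against the single exposure. In the H1 preincubations, tonic acetylcholine, dopamine and the 3 transmitters gave 302 and 26, 47 and 9, and 134 and 7, and tonic glutamate 0 and 18 (10 of 10). Phasic dopamine after ascorbic acid, glutamate and the 3 transmitters gave 3 and 2, 6 and 2, and 9 and 11 (2 of 10 for the last), and after acetylcholine and dopamine 0 and 0 (10 of 10 each). In H9, the tonic 3 transmitters gave 19401 and 0 and phasic dopamine after ascorbic acid, dopamine and the 3 transmitters 21 and 1, 677 and 2, and 20251 and 0. All 10 of 10 splits were as large for tonic acetylcholine (0 and 0), dopamine (0 and 1) and glutamate (0 and 0) and for phasic dopamine after acetylcholine and glutamate (0 and 0 each).

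For the means over preincubations and the remaining tests of a difference, 40 or 100 splits were counted. The H1 phasic response gave 26 genes and at most 0 in the others (1 of 40, the lowest share that 40 splits can give). Chance is unlikely by this count but is not excluded, and the replicates may be technical. The H9 phasic response gave 6642 against up to 19943 (3 of 40), so chance cannot be excluded. The H1 response differing among preincubations gave 0 and 0 (40 of 40), and the difference between lines after 5 days and 24 h gave 0 against up to 1358 (100 of 100).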

How the results depend on the processing

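The alternatives exon reads, leaving out the 9 mostly intronic libraries, both together, and the same-stamp reference were chosen after the result was seen. Of 764 alternative values of named genes, 736 kept their direction and their side of the threshold. Counts are of genes past the threshold, within 1.5 times the reported count unless given here, and where a count moved the cause was not tested. The H9 preincubation comparisons hold 9 libraries with few reads, mostly in introns, and the numbers of higher and lower genes changed with the scaling.

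In exon reads, 27 of 53 counts stayed within 1.5 times. The others were 6476 for dopamine on 5 days in H1, 2690 and 2820 for the H9 groups labelled 1 h and 24 h, 1963 for H9 5-day against the single exposure and 118 for H9 after 5 days and 24 h. For SKF82958 against SKF81297, SKF81297 against quinpirole and quinpirole with CGS21680 against quinpirole they were 677, 2352 and 2488. Tonic acetylcholine, glutamate and the 3 transmitters in H1 gave 2, 2 and 55; phasic dopamine in H1 gave 9, 4, 4, 10 and 2 after ascorbic acid, acetylcholine, dopamine, glutamate and the 3, and 58 pooled. In H9, tonic acetylcholine and the 3 gave 2248 and 14342, and phasic dopamine after acetylcholine, glutamate and the 3 gave 0, 0 and 14412. The differences between lines gave 600, 11214, 1130 and 8. The median over shared genes of the log2 change in exon reads minus that in all reads was 0.21, 0.28, 0.36 and 0.14 for the H1 dopamine groups in the order 1 h, 24 h, 5 days, 5 days and 24 h, and -0.18 and -0.2 for the H9 groups labelled 1 h and 24 h.

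DESeq2 in place of edgeR kept 27 of 53 counts within 1.5 times. It gave 1005 and 385 for H9 after 5 days without and with 24 h, and 488, 2448 and 2423 for the agonist comparisons in the order above. In H1 it gave 11, 10, 8 and 23 for tonic acetylcholine, dopamine, glutamate and the 3, and 8, 4, 3, 14 and 4 for phasic dopamine after the preincubations in the order above, 45 pooled and 1 differing among them. In H9 it gave 10235, 10 and 89 for tonic acetylcholine, dopamine and glutamate, 14, 2199, 11 and 4205 for phasic dopamine after ascorbic acid, acetylcholine, dopamine and glutamate, and 11695 pooled. Between lines it gave 190 after 5 days and 24 h and 12262 for the phasic response. DESeq2 size factors in edgeR gave 67 for H9 after 5 days and 24 h, 1 for H1 phasic dopamine after acetylcholine, 4281 for H9 tonic acetylcholine and 9751 for the phasic line difference. The median change per gene with them was 0.14 for H1 on 5 days and -0.33, -0.11 and -0.18 for the first 3 line differences.

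Without a filter on low counts, SKF81297 against quinpirole and quinpirole with CGS21680 against quinpirole gave 977 and 991, H1 phasic dopamine 1 after ascorbic acid, 1 after acetylcholine and 17 pooled, and H9 phasic dopamine 0 after glutamate and 4009 pooled. Uniquely mapped reads gave 2 for H1 tonic dopamine, 1 for H1 and 0 for H9 phasic dopamine after acetylcholine and 72 for H9 after 5 days and 24 h. With the replicate number as a block, 48 of 51 counts stayed within 1.5 times, and the others were 1 for H1 phasic dopamine after acetylcholine, 24 for H9 after 5 days and 24 h and 7 for H9 phasic dopamine pooled. In a check of pairing, the same number gave the best match for 13 of 45, 5 of 15 and 10 of 30 libraries of the H1 exposures, H9 exposures and H1 preincubations, with a median correlation of 0 to 0.01. In the H9 preincubations it did for 12 of 18 (median correlation 0.04 against -0.03 for other numbers), so a pairing is left open there.

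Against the other groups of the file stamp, the counts for SCH23390, sulpiride, both antagonists with dopamine, SKF81297, SKF82958, quinpirole, CGS21680 and quinpirole with CGS21680 were 907, 1069, 1025, 277, 226, 1536, 11646 and 687. Without the 9 mostly intronic libraries H9 gave 3 for tonic dopamine and 40, 387 and 45 for phasic dopamine after ascorbic acid, dopamine and glutamate. Over these preincubations alone it gave 545 pooled and 2 differing, and the line difference, with H1 over the same ones, gave 18. In exon reads without the 9 libraries these were 3, 35, 1178, 104, 905, 7 and 22, with 2 for tonic glutamate (2 libraries left). Tonic acetylcholine had 1 library left, so no test of groups. The comparisons whose groups lost all libraries have no value there.

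Directions reversed for FOS in antagonists with dopamine on 5 days against dopamine on 5 days, which did not pass, at -0.09 with DESeq2, -0.09 with its size factors and -0.32 in exon reads, and for ASPM in the H9 phasic response with all libraries, at 0.82 in exon reads. PPP1R1B after 5 days in H1 no longer passed in exon reads (-0.37), nor did PDIA2 under tonic dopamine (-0.99) and HMOX1 between lines (-1.75). With the replicate block 11 named values no longer passed, among them FOSB in SKF82958 against SKF81297 (-1.56), CCN2 in H1 phasic dopamine after glutamate (1.21), and in the phasic means FOS in H1 (0.56) and FOS in H9 (2.94).

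With an estimated in place of a preset correlation, the number of 51 comparisons past the threshold went from 44 to 14 for immediate early genes, 29 to 0 for MAP kinase feedback, 16 to 3 for cAMP and CREB targets, 3 to 1 for striatal projection neuron markers, 9 to 3 for glutamate receptors, 9 to 2 for GABA receptors, 28 to 0 for synaptic genes and 24 to 2 for NRF2 targets. It went from 23 to 0 for heat shock, 37 to 1 for unfolded protein response, 29 to 2 for hypoxia, 13 to 2 for metal response, 33 to 0 for p53 targets, 3 to 0 for NF-kappaB, 3 to 0 for interferon, 32 to 1 for cholesterol synthesis and 41 to 13 for cell cycle. Among cell types and organelles it went from 37 to 2 for neural progenitors, 27 to 7 for astrocytes, 26 to 0 for cortical neurons, 1 to 0 for interneurons, 18 to 0 for mesenchymal genes, 18 to 6 for choroid plexus and 12 to 0 for pluripotency. For mitochondrially encoded genes, ribosomal proteins, oxidative phosphorylation, histones and neuropeptides it went from 19 to 0, 40 to 0, 36 to 0, 11 to 2 and 10 to 0. Acetylcholine receptors went from 5 to 4, and dopamine receptors and oligodendrocytes had 0 either way.

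Leaving out 1 library at a time gave these ranges in the H1 exposures: 2289 to 3556 for dopamine (2289 and 2699 without dopamine replicate 2 and 3, 2656 without PBS replicate 3), 7063 to 10864 for 5 days (lowest without replicate 1 of that group), and 1283 to 3511 for 5 days and 24 h (1404 and 1283 without PBS replicate 1 and 3, 1333 without treated replicate 2). For 5-day against single exposure it was 2058 to 3867 (2135 without single replicate 3, 2058 without 5-day replicate 2), for glutamate 3229 to 4544 (lowest without glutamate replicate 3), for quinpirole 3836 to 5193 (lowest without quinpirole replicate 2), for CGS21680 3919 to 7245 (lowest without its replicate 1) and for antagonists with dopamine against dopamine 7289 to 10545 (lowest without antagonist replicate 3). SKF82958 against SKF81297 gave 91 to 756, with 136, 114 and 162 without SKF81297 replicates 1, 2 and 3 and 171, 91 and 756 without those of SKF82958. SKF81297 against quinpirole gave 440 to 1958, with 574 and 440 without SKF81297 replicates 2 and 3 and 761 and 869 without quinpirole replicates 1 and 2. Quinpirole with CGS21680 against quinpirole gave 794 to 1338, with 794, 817 and 983 without quinpirole replicates 1, 2 and 3 and 797 and 997 without replicates 1 and 3 of the combination.

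In the H9 exposures the range was 32 to 128 after 5 days (53, 32 and 128 without PBS replicates 1, 2 and 3; 64, 41 and 66 without those of the treated group) and 2 to 67 after 5 days and 24 h (2, 2 and 67 without PBS replicates; 2, 11 and 5 without treated ones). The line difference after 5 days and 24 h gave 0 to 608 (608 without H1 treated replicate 1, 4 without H9 treated replicate 3, 2 without H9 PBS replicate 3), and the phasic line difference 3777 to 8690 over the 8 libraries drawn (3777 without replicate 1 of H1 tonic ascorbic acid with phasic dopamine).

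In the H1 preincubations the range was 0 to 2 for tonic dopamine (0 and 2 without replicates 1 and 3 of that group). Phasic dopamine gave 0 to 1 after ascorbic acid (1 without dopamine replicate 1 or 2, 0 without any other), 0 to 1 after acetylcholine (0 without ascorbic replicate 2 or 3 or dopamine replicate 1, 1 without any other), 0 to 3 after dopamine (3 without dopamine replicate 3), 0 to 4 after glutamate (4 without dopamine replicate 2, 0 without any other) and 0 to 2 after the 3 (0 without ascorbic replicate 3, 2 without dopamine replicate 3). Pooled it gave 14 to 46: 46 without replicate 3 of tonic and phasic dopamine, 14 and 17 without ascorbic replicates 3 and 2 and 15 without dopamine replicate 3 after ascorbic acid, 16 without ascorbic replicate 3 and 15, 17 and 17 without dopamine replicates 1 to 3 after acetylcholine, 15 and 16 without replicate 1 of either after dopamine, 17 without ascorbic replicate 2 or 3 after glutamate, and 16 without ascorbic replicate 1 or 2 and 17 and 15 without dopamine replicates 1 and 3 after the 3. The test among preincubations gave 0 to 1 (1 without dopamine replicate 3 after the 3).

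In the H9 preincubations, tonic acetylcholine gave 0 to 21959 (highest without its replicate 1). Phasic dopamine gave 2 to 2190 after acetylcholine (6, 2190 and 1093 without ascorbic replicates 1, 2 and 3, 4 without dopamine replicate 2), 0 to 1 after dopamine (1 without ascorbic replicate 2) and 0 to 1 after glutamate (0 without ascorbic replicate 2 or dopamine replicate 1). Pooled it gave 7 to 19193: 7 without ascorbic replicate 2 and 4238 without dopamine replicate 1 after ascorbic acid, 19193, 3463 and 2712 without ascorbic replicates 1 to 3 after acetylcholine, 3923 without ascorbic replicate 2 and 3439 without dopamine replicate 3 after dopamine, 23 without ascorbic replicate 3 and 3832 without dopamine replicate 1 after glutamate, and 4386 and 3679 without dopamine replicates 2 and 3 after the 3. The test among preincubations gave 6914 to 17034 (7343, 7224 and 6922 without ascorbic replicates 1 to 3 and 7625 and 6914 without dopamine replicates 2 and 3 after the 3).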

Other observations

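Further gene groups moved in comparisons described above. In H1 on 5 days of dopamine against the single exposure, 6 of 22 glutamate receptor genes and 3 of 15 GABA receptor genes were higher and 0 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0087 and 0.037 with an estimated correlation), and 19 of 22 cholesterol synthesis genes were lower (19 adjusted over the list alone; adjusted p = 0.04 with an estimated correlation). In H1 with both antagonists and dopamine on 5 days against PBS, 5 of 10 metal response genes were higher (6 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation) and 6 of 20 acetylcholine receptor and handling genes with 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.029 with an estimated correlation). In H9 on 5 days of dopamine, 1 of 7 replication-dependent histone genes was higher (4 adjusted over the list alone; adjusted p = 0.02 with an estimated correlation).

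Choroid plexus and ciliated epithelium markers differed in several H1 comparisons. With SKF82958 and with quinpirole 6 and 5 of 12 were lower than PBS, across the file stamps, with 1 and 0 higher (7 and 6 lower adjusted over the list alone; adjusted p = 0.044 and 0.033 with an estimated correlation). Adding CGS21680 to quinpirole raised 5 of 12 (8 adjusted over the list alone; adjusted p = 0.0039 with an estimated correlation). Under tonic glutamate in H1 the list had a median of 0.50, with 0 of 12 past the threshold over all genes (2 adjusted over the list alone; adjusted p = 0.0027 with an estimated correlation).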
